A study of Homo sapiens with 27 samples.

How the data were processed

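Human keratinocytes, the main cell type of the epidermis, were cultured alone (control), with 1 of 4 single stimuli, or with 1 of 4 combinations. The single stimuli were the bacteria Staphylococcus aureus (SA) and Streptococcus pyogenes (SP) and the cytokines interleukin-17A (IL17) and tumour necrosis factor alpha (TNF). The combinations joined each bacterium with each cytokine and are written SA.IL17, SA.TNF, SP.IL17 and SP.TNF. Each of the 9 groups held 3 arrays, 27 in all. Dose and exposure time are not given in the sources used here. The labels do not say whether the arrays of a group came from separate cultures or donors, so the p-values measure only the spread between these samples, which may be technical. The series also names quantitative PCR and a multiplex protein assay, which were not analysed here.

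Per the labels, total RNA was purified with a Qiagen RNeasy kit, amplified in 2 cycles, labelled with biotin and hybridised to Affymetrix GeneChip arrays. The deposited values are log2 expression values from GCRMA, a method that corrects the background by probe sequence, normalizes between arrays and summarises the probes of a probe set, per the submitters' processing notes. Its version is not given in the sources used here. The values ran from 1.66 to 13.7, and the median per array lay between 5.99 and 6.10. For arrays, their number per group limits the precision. No further normalization was applied.

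The table held 54675 probe sets, and no column of it was left unused. The platform's annotation gave 1 gene for 41097 of them and several for 1801, and 11777 were not listed in it and are unnamed here. Symbols were updated through Entrez identifiers with a RefSeq gene table of assembly GRCh38.p14, used only for names. Of the probe sets with 1 gene, 41043 matched that table and 54 kept the platform's symbol. In all, 58 probe sets of Y-linked genes or of the X-linked gene XIST were left out, and other X-linked genes were kept. For each of the 19741 genes, the probe set of highest mean over all arrays was kept. Genes above a log2 value of 4 on at least 3 arrays were tested, which kept 16854 and removed 2887. Of all values, 24.0% lay at or under 4, where background dominates and folds are compressed. Paralogous genes of near-identical sequence, such as S100A7 and S100A7A, can share probe signal.

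All 27 arrays were fitted in 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3), with 18 residual degrees of freedom and 2.96 prior ones. From it came 20 contrasts: each of the 8 stimulated groups against control, each combination against its bacterium alone, SA against SP, IL17 against TNF, SA.IL17 against SP.IL17, SA.IL17 against SA.TNF, and the 4 interactions. An interaction is the combination's change from control minus the summed changes of its bacterium and its cytokine, on the log2 scale. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 with at least a 2-fold difference. A moderated F test asked whether a gene differed over any of the 9 groups. Errors of log2 differences are moderated standard errors (SE), and the adjusted p-values of single genes are limma's.

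Gene lists were fixed from general knowledge before the data were examined, as were the groups, the fits, the rule for named genes and the alternatives. The 36 lists were a key panel, antimicrobial peptides, neutrophil attractants, chemokines for other leukocytes, the IL-1 family, other cytokines, NF-kB targets, the type I interferon response, interferons, a psoriasis and IL-17 signature (called the psoriasis list), keratinocyte differentiation, cornified envelope genes of the SPRR and LCE families, basal keratinocyte genes, hyperproliferation keratins, cell cycle, proteases and wound genes, hypoxia and glycolysis, unfolded protein and amino acid stress, heat shock, cholesterol synthesis, oxidative stress (NRF2 targets), metallothioneins, immediate early genes, pattern recognition, antigen presentation by MHC class I and by class II, cell death, p53 targets, junctions, kynurenine and nitric oxide, complement, ribosomal proteins, and markers of melanocytes, fibroblasts, endothelial cells and leukocytes. Lists with at least 5 tested members were tested in each contrast with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. The test fry asked whether a list's genes moved, on balance, one way. List p-values are Benjamini-Hochberg adjusted over the lists of a contrast. Counts of changed members are over all genes tested, and the count adjusted over the list alone is given beside each printed count from which it differed.

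Genes were named by a fixed rule. Against control, these were the 10 highest and 10 lowest changed genes whose samples did not overlap between the groups, and in other contrasts the 5 highest and 5 lowest, for interactions without the overlap condition. The rule added the members of the key panel in every contrast and, per list, up to 4 members of largest change. Fibroblast, endothelial, melanocyte and leukocyte markers served as signs of other cell types, and the difference between the 3' and 5' control probe sets of GAPDH as a sign of RNA quality. That ratio was picked after control probe set values had been seen.

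An unexplained number in the labels' descriptions divides the arrays into 4 sets, each group lying in 1 set: control with SP.TNF, IL17 with TNF, SA with SP, and SA.IL17 with SA.TNF and SP.IL17. It was treated as a possible batch. Of the 20 contrasts, 5 lie within 1 set: SP.TNF against control, SA against SP, IL17 against TNF, SA.IL17 against SP.IL17, and SA.IL17 against SA.TNF. In the others, this number and the groups cannot be told apart.

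Alternatives were other filters at log2 values of 5 and 6 or none, the probe set of largest interquartile range, the mean of a gene's probe sets, every probe set (those without a single gene included), quantile normalization, median centring, array weights, trend and robust eBayes, only the groups compared, an additive model of bacterium, cytokine and description number over all 27 arrays with the number as a fixed block (for SA against SP and IL17 against TNF), at least 1.5-fold, adjusted p alone, and leaving out each array in turn. A check of list medians under other scalings, a fit with values under 4 set to 4, and a fit with the order of the arrays in their group as a block were added after the data were seen. Replicates were compared before averaging, and the share of identical values between 2 arrays of a group was at most 0.00441, so none was a copy of another, while repeat hybridisations of 1 culture are not excluded. The fit was tested on simulated data for SA against control over 16854 genes with 200 changed. It called 22 of 50 genes changed by 2-fold, and all 50 of each set of 50 changed by 3-, 4- and 8-fold, with 0 false calls. Of the 2-fold genes, 48 passed the adjusted p alone, and so did 18 of the unchanged genes. At an unadjusted p under 0.05, 1 of 100 simulated unchanged lists was called by camera. The simulated genes were drawn independently, so this does not test the lists under the correlation that members of real lists can have.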

Results

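Expression was measured on 27 arrays of human keratinocytes, 3 for each of 9 groups: an untreated control, the bacteria SA (Staphylococcus aureus) and SP (Streptococcus pyogenes), the cytokines IL17 (interleukin-17A) and TNF (tumour necrosis factor alpha), and the 4 combinations of a bacterium with a cytokine. The series asks whether the bacteria induce expression patterns related to psoriasis, an inflammatory skin disease, and whether the cytokines augment them. Values are the submitters' GCRMA log2 values, differences are log2 fold changes with their SE from limma, and n = 3 arrays in every group. Replicates differed by a root mean square of 0.136 to 0.260 over the tested genes. Every gene named by rank in a comparison with control had sample values that did not overlap between the 2 groups, so all 3 stimulated arrays showed the direction given. Chance gives such a separation for 10% of genes. For the genes most affected by group means near or under the background level of 4, the difference with values under 4 set to 4, an alternative added after the data were seen, is given as well.

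Arrays separated by stimulus, except that SA and SP overlapped on the first and second principal components. Of 16854 genes tested, 13583 (80.6%) differed over the groups by the moderated F test. The first principal component held 43.2% of the variance. It placed the controls between -35.0 and -33.1, the bacteria alone between -30.8 and -27.4, the single cytokines between -19.7 and -9.05, and the combinations between 20.9 and 41.2. The next component held 33.2% and parted the combinations by cytokine, those with IL17 between -33.7 and -24.6 and those with TNF between 33.2 and 40.2.

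**Figure D1:**
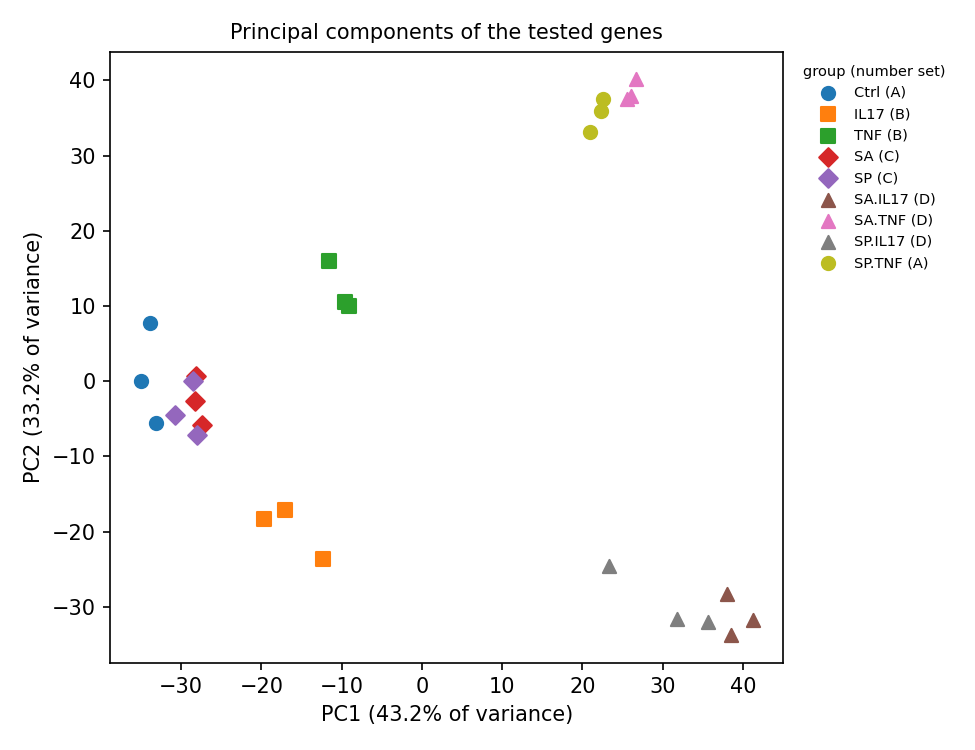
Scores of the 27 arrays on the first and second principal components of the tested genes (arbitrary units, with the percent of variance on each axis), 1 point per array and 3 arrays per group, coloured by group. Combinations lie at first-component scores of 20.9 to 41.2 and all other arrays at or below -9.05.

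The number of changed genes was lowest with a bacterium alone and highest with the combinations. SA changed 33 genes and SP 25, IL17 changed 177 and TNF 381, while the combinations changed 1261 (SA.IL17), 1045 (SA.TNF), 964 (SP.IL17) and 909 (SP.TNF). Sample values did not overlap for 32 of the 33, 24 of the 25, 175 of the 177, all 381, 1259 of the 1261, all 1045, 963 of the 964 and 907 of the 909, respectively. Of these 8 comparisons, only SP.TNF lies within 1 set of the unexplained description number, so for the others the group and that number cannot be told apart.

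**Figure D2:**
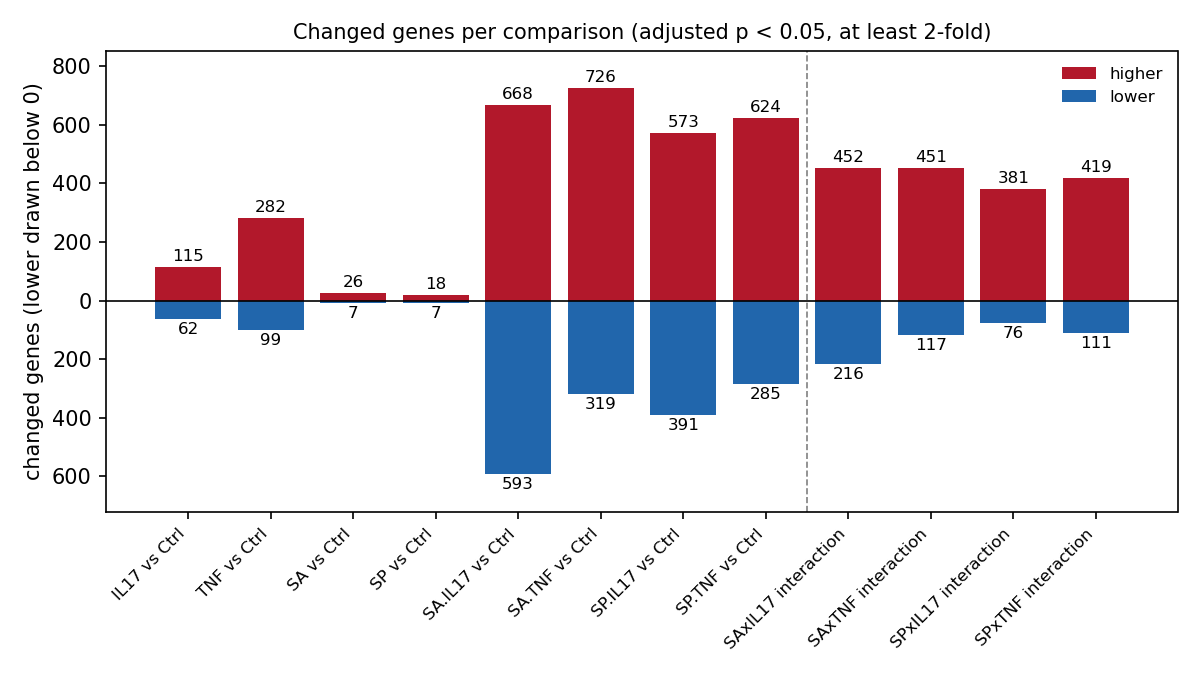
Number of genes changed against control in each of the 8 stimulated groups (n = 3 arrays each, limma, adjusted p under 0.05 and at least 2-fold), higher genes drawn upwards and lower genes downwards from 0. Bars against control run from 18 higher and 7 lower with SP to 668 higher and 593 lower with SA.IL17, and to 726 higher with SA.TNF.

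S. aureus alone raised the cytochrome genes CYP1A1 and CYP1B1 and members of the antimicrobial, IL-1 family and neutrophil attractant lists. CYP1A1, a monooxygenase induced through the aryl hydrocarbon receptor, rose 4.67-fold (log2 2.22 ± 0.13, adjusted p = 1.08e-09), and its relative CYP1B1 rose by 1.29 ± 0.13. The S100 protein gene S100A7A rose by 1.81 ± 0.14, S100A7 (psoriasin, antimicrobial) by 1.08 ± 0.12, and IL36RN, which encodes the IL-36 receptor antagonist, by 1.6 ± 0.08. IL1B rose by 1.36 ± 0.19, IL36G by 1.00 ± 0.08 and CCL20, which attracts T cells bearing CCR6, by 1.02 ± 0.15. The neutrophil attractant CXCL5 rose by 1.49 ± 0.19. CXCL10 and CXCL11, which attract T cells bearing CXCR3, rose by 1.28 ± 0.34 and 1.58 ± 0.45 (adjusted p = 0.0191 and 0.0275), CXCL11 by 1.40 with values under 4 set to 4. SPRR2G, a cornified envelope gene, rose by 1.37 ± 0.14, and SPINK1, a trypsin inhibitor, by 1.26 ± 0.12. The 7 lower genes were LINC00115 (-1.11), PARM1 (-1.08), LOC100272217 (-1.06), the spindle gene ASPM (-1.06), CCDC3 (-1.03), TXNIP, which encodes a thioredoxin inhibitor, and SYDE2, the last of them just past 2-fold and at -0.61, not called, with values under 4 set to 4. Of the 7 lower genes, 3 were also lower with SP.TNF, which shares the controls' description number, and 1 was higher. Of the 26 higher genes, 25 were also higher with SP.TNF. Centring arrays on their medians gave 34 higher and 4 lower genes in place of 26 and 7.

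Among the fixed lists, the psoriasis list was higher with SA (5 of 30 members called higher, none lower, median 0.35, camera adjusted p = 1.62e-17). It shares 13 tested members with the key panel and 8 with the antimicrobial list, so these are not separate lines of evidence. In the key panel 5 of 25 members rose (median 0.35, adjusted p = 6.76e-14), in the IL-1 family 3 of 15 (adjusted p = 1.55e-09), in the antimicrobial list 2 of 16 (adjusted p = 3.79e-08), among neutrophil attractants 2 of 8 (adjusted p = 4.09e-06), and among SPRR and LCE genes 3 of 15 (adjusted p = 2.30e-09). These camera calls held with an estimated correlation (adjusted p from 4.70e-05 to 0.0128). NF-kB targets and other cytokines had 1 member called each (of 25 and 20, adjusted p = 3.24e-07 and 0.00125), and both calls held at adjusted p = 0.0359 and 0.0349 with an estimated correlation. Of 14 chemokines for other leukocytes 3 rose (adjusted p = 9.05e-04, but adjusted p = 0.0653 with an estimated correlation). Of 32 interferon-response genes 1 was called higher, and 0 adjusted over the list alone (camera adjusted p = 1.05e-04, but 0.512 as adjusted p with an estimated correlation). Among the members of the key panel that did not pass were CXCL8 (0.77), LCN2 (0.90), IL6 (0.73), FLG (0.88), TNF (0.45), MKI67 (-0.52) and IL19 (-0.08). Each of these lay under the 2-fold minimum, so not passing does not show that they were unchanged.

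With S. pyogenes alone, S100A7A rose 5.32-fold (2.41 ± 0.14, adjusted p = 8.71e-10), S100A7 by 1.31, CXCL5 by 1.47, IL36RN by 1.28, IL36G by 1.21, IL1B by 1.27, CCL20 by 1.15, SPRR2G by 1.24 and CYP1A1 by 1.30. The hyaluronan-binding protein gene TNFAIP6 rose by 1.42 ± 0.35 (adjusted p = 0.0181). IL6 (1.13 ± 0.16) and the neutrophil attractant CXCL8 (2.02-fold) also passed. The lower genes included LOC100272217 (-1.29, and -1.16 with values under 4 set to 4), LINC00115 (-1.13), ZNF143-AS1 (-1.13) and the collagen gene COL1A2 (-1.27 ± 0.36, adjusted p = 0.0344), whose sample values overlapped with control and which was the 1 of 13 fibroblast markers called (list adjusted p = 0.212). Of the 7 lower genes, 0 were also lower with SP.TNF, which shares the controls' description number, and 1 with SP.IL17. Of the 18 higher genes, 17 were also higher with SP.TNF. For the lower genes, an effect of SP and a difference tied to the number cannot be told apart. The psoriasis list was higher (8 of 30 called, median 0.38, adjusted p = 5.16e-23, adjusted p = 3.19e-05 with an estimated correlation), as were the key panel (6 of 25, adjusted p = 3.12e-13), the antimicrobial list (3 of 16, adjusted p = 1.12e-08), neutrophil attractants (3 of 8, adjusted p = 1.43e-07), the IL-1 family (3 of 15, adjusted p = 5.65e-08), SPRR and LCE genes (1 of 15, adjusted p = 2.97e-06) and NF-kB targets (1 of 25, adjusted p = 1.57e-08). These calls held with an estimated correlation (adjusted p at most 0.0234). Cell cycle genes had a median of -0.19 with 0 of 30 called (camera down, adjusted p = 5.21e-04, but adjusted p = 0.375 with an estimated correlation). The count of 25 changed genes became 39 without Ctrl replicate 2 and 20 without SP replicate 3.

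Few genes differed between the 2 bacteria. Both raised 13 genes and lowered 2, against 0.0278 and 0.00291 expected of independent lists and at most 0 in simulations of unchanged groups sharing the controls. Unchanged groups give almost no calls, so these simulated counts cannot show how much overlap shared controls add among called genes. The fold changes of SA and SP correlated at 0.784 across genes, which are not independent replicates, and unchanged groups sharing these controls gave 0.50. The covariance was 0.0257 against 0.00546 simulated. The 3 controls could not be split, so part of the excess may come from them. SA and SP also share a description number that the controls do not. A difference tied to that number would enter both changes alike. The simulation left it out, so it cannot be told apart from a shared response. Between SA and SP, 1 gene passed: ATP6V0D2, a subunit of the vacuolar proton pump, was 1.21 ± 0.21 higher with SA (adjusted p = 0.0141). At an unadjusted p under 0.05 in limma, 1268 of 16854 genes passed, where chance alone gives a share of about 0.05. At the adjusted p alone, 16 passed. The interferon-response list was higher with SA than with SP (median 0.49, 0 of 32 called, 5 adjusted over the list alone, adjusted p = 3.01e-27), but adjusted p = 0.110 with an estimated correlation. The psoriasis list had a median of -0.08 with 0 of 30 called (camera down, adjusted p = 0.00282, but adjusted p = 0.188 with an estimated correlation). CXCL10 was 1.15 higher with SA and did not pass. The count was 2 without SA replicate 1, 0 without SA replicate 2, and 3 higher and 1 lower under median centring. With the order of the arrays in their group as a block, added after the data were seen, it was 4 higher and 2 lower.

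IL-17A alone raised members of the antimicrobial and cornified envelope lists and lowered members of the interferon-response list. S100A7A rose 27.9-fold (4.80 ± 0.14, adjusted p = 2.49e-16) and S100A12, a neutrophil-associated S100 protein gene, by 3.50 ± 0.10. The vanin pseudogene VNN3P rose by 4.00 ± 0.17, SPRR2G by 3.33 ± 0.14, IL1B by 2.84 ± 0.19, the amino acid transporter gene SLC6A14 by 2.65, the prostaglandin E2 receptor gene PTGER3 by 2.65, SERPINB4, a serine protease inhibitor, by 2.55 ± 0.07, and COXFA4L3 by 2.76. LCN2, which binds bacterial siderophores, rose by 2.36 ± 0.20, IL36G by 2.33, S100A7 by 2.05, CCL20 by 2.04, CXCL8 by 1.71, IL23A, a subunit of IL-23, by 1.27 and IL6 by 1.14. IFI44 fell by 2.32 ± 0.27, IFIT2 by 2.20 ± 0.53, IFI44L by 2.11, IFIT1 by 2.04 ± 0.36, MX2 by 1.68, SAMD9L by 1.68 and IFIT3 by 1.65, all interferon-induced. The collagen gene COL1A2 fell by 1.87 ± 0.36, HMCN1 by 1.81, SCUBE2 by 1.67 and the gelatinase gene MMP9 by 1.03.

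With IL17, 15 of 30 genes of the psoriasis list rose and none fell (median 1.07, adjusted p = 1.20e-32). In the key panel 8 of 25 rose and 2 fell (adjusted p = 6.20e-12), in the antimicrobial list 4 of 16 rose (adjusted p = 6.41e-15), among neutrophil attractants 5 of 8 (median 1.16, adjusted p = 4.68e-07), in the IL-1 family 5 of 15 (adjusted p = 4.45e-09) and among SPRR and LCE genes 6 of 15 (adjusted p = 5.77e-08). These held with an estimated correlation (adjusted p at most 0.00667). Of 32 interferon-response genes 15 fell and none rose (median -0.91, adjusted p = 1.66e-13), but adjusted p = 0.153 with an estimated correlation. Differentiation genes had 4 of 27 higher, with TGM1 at 1.5 and ALOX12B, a lipoxygenase of the skin barrier, at 1.59 (adjusted p = 3.02e-04, but adjusted p = 0.438 with an estimated correlation). Of the fibroblast markers 1 of 13, COL1A2, was lower (adjusted p = 0.0909).

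TNF-α alone raised members of the cornified envelope, chemokine and protease lists. S100A7A rose 14.9-fold (3.90 ± 0.14, adjusted p = 1.08e-14). The barrier genes FLG2 (3.21 ± 0.25), LCE3D (3.14 ± 0.10), SPRR2G (3.09) and FLG, which encodes filaggrin (2.30 ± 0.22), rose, with the filaggrin-processing protease gene ASPRV1 at 2.93. CCL2, a monocyte attractant, rose by 3.20 ± 0.38, MMP9 by 3.10 ± 0.17, the collagenase gene MMP13 by 2.99, the Fc receptor gene FCGR3B by 3.21, ELMOD1 by 3.20, AZGP1 by 3.09 and DEPP1 by 3.04. TNF itself rose by 2.14 ± 0.10, CXCL10 by 2.14 ± 0.34, IL1B by 2.19, IL23A by 2.13, IL6 by 1.84 and the adhesion molecule gene ICAM1 by 2.63. PLAC8 fell by 2.41, the mitotic kinase gene PBK by 2.26 ± 0.16, IGFBP5, which binds insulin-like growth factors, by 2.21, the alcohol dehydrogenase gene ADH7 by 2.14, DEPDC1 by 1.99 (-1.47 with values under 4 set to 4) and the adrenergic receptor gene ADRB1 by 1.87.

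With TNF, 18 of 30 genes of the psoriasis list rose (median 1.20, adjusted p = 4.11e-25), 13 of 25 of the key panel (adjusted p = 1.63e-15), 9 of 25 NF-kB targets (median 0.71, adjusted p = 2.03e-18), 7 of 14 chemokines for other leukocytes (adjusted p = 1.35e-04), 7 of 15 SPRR and LCE genes (adjusted p = 1.61e-10) and 6 of 23 proteases (adjusted p = 5.29e-07). The IL-1 family had 7 of 15 higher and 1 lower (adjusted p = 2.43e-08). These held with an estimated correlation (adjusted p at most 0.0319). Of 27 differentiation genes 11 rose (adjusted p = 6.65e-10, but adjusted p = 0.0867 with an estimated correlation). Of 32 interferon-response genes 5 rose (median 0.60, adjusted p = 5.16e-08, but adjusted p = 0.272 with an estimated correlation). Of 30 cell cycle genes 6 fell (median -0.24, adjusted p = 0.00120, but adjusted p = 0.305 with an estimated correlation), TOP2A by 1.56 and RRM2 by 1.36. Fibroblast markers had 2 of 13 higher (LUM 1.66 and PDGFRA 1.02, adjusted p = 0.241), leukocyte markers 2 of 10 (adjusted p = 0.0148, but adjusted p = 0.0763 with an estimated correlation) and endothelial markers 2 of 8 (adjusted p = 0.126).

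The 2 cytokines, which share a description number, differed in 355 genes, 97 higher with IL17 and 258 higher with TNF. IL17 gave more ADRB1 (2.36), VNN3P (2.25), the transcription factor gene FOXA2 (2.07), C4orf54 (2.05), ATP6V0D2 (2.00) and LCN2 (1.26). It gave less MMP13 (-4.20), MMP9 (-4.14), the interferon-induced CMPK2 (-3.63), the skin chemokine gene CCL27 (-3.55), GRIN2A (-3.27), CXCL10 (-2.73), IFIT1 (-2.52) and FLG (-1.62). Of 32 interferon-response genes 24 were lower with IL17 (median -1.50, adjusted p = 6.53e-29, but adjusted p = 0.0846 with an estimated correlation). Of 16 MHC class I genes 2 were lower (adjusted p = 1.28e-11, held at adjusted p = 0.00712 with an estimated correlation). The psoriasis list had 3 genes higher and 1 lower (adjusted p = 0.0334, but adjusted p = 0.321 with an estimated correlation). Of 13 fibroblast markers 3 were lower with IL17 (adjusted p = 0.00532, but adjusted p = 0.321 with an estimated correlation).

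S. aureus with IL-17A gave IL19, a cytokine gene of the IL-10 family that was not called with either stimulus alone (IL17 0.91, SA -0.08). Its mean was 4.09 ± 0.18 (SD, n = 3) in control, at the background level, and 11.4 ± 0.14 with SA.IL17 (difference 7.26 ± 0.19, adjusted p = 2.13e-17). NDP, which encodes the Wnt receptor ligand norrin, rose by 6.96 ± 0.23, the adhesion molecule gene CEACAM6 by 6.89, COXFA4L3 by 6.63, S100A12 by 6.15 ± 0.10, IL1F10, an IL-1 family cytokine gene, by 5.85, SPRR2C by 5.84, LCE2B by 5.79, PSORS1C2, which lies in a psoriasis susceptibility region, by 5.74 and S100A7A by 5.65. IL23A rose by 5.42 ± 0.24, IL6 by 4.68, IL1B by 4.56, CXCL8 by 3.48, MKI67, a marker of cycling cells, by 2.14 ± 0.20 and IL17C by 1.76. The selenium transporter gene SELENOP fell by 5.22 ± 0.33, IGFBP5 by 4.46, the matrix protein gene ASPN by 4.41, TMT1A by 3.83, DAPL1 by 3.69, the small heat shock protein gene HSPB3 by 3.24, TLR3, a receptor for double-stranded RNA, by 3.14 ± 0.24 and the glutamate transporter gene SLC1A2 by 3.07. With values under 4 set to 4, IL19 gave 7.23, NDP 6.14, CEACAM6 6.78 and TLR3 -2.96. Median centring moved the median of all genes by 0.11 in this contrast.

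S. pyogenes with IL-17A was led by IL19 as well. IL19 rose by 7.79 ± 0.19 from that background level (adjusted p = 5.68e-18), CEACAM6 by 6.49, NDP by 6.38, COXFA4L3 by 6.35, S100A12 by 6.02, SPRR2C by 5.75, S100A7A by 5.70, IL1F10 by 5.63, VNN3P by 5.49 and the neutrophil attractant CXCL6 by 5.47. IL23A rose by 5.14, IL6 by 5.06, IL1B by 4.52 and MKI67 by 2.07. IGFBP5 fell by 4.13, ASPN by 4.02, SELENOP by 3.53, DAPL1 by 3.42, HSPB3 by 3.29 and the protease gene CAPN14 by 2.87. With values under 4 set to 4, IL19 gave 7.76, CEACAM6 6.38, NDP 5.57 and CXCL6 4.89. The 2 combinations with IL17 shared 527 higher and 346 lower genes, against 22.7 and 13.76 expected of independent lists. Their covariance was 0.343 against 0.00546 simulated for shared controls. These 2 groups also share a description number that the controls do not. The simulation left this out, so part of the overlap may be tied to the number.

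Of 30 genes of the psoriasis list, 25 rose and 1 fell with SA.IL17 (median 2.74, adjusted p = 6.89e-28) and 26 rose with SP.IL17 (median 2.54, adjusted p = 4.08e-30). Antimicrobial genes rose for 10 and 11 of 16 (adjusted p = 5.77e-14 and 8.72e-15), neutrophil attractants for 7 of 8 in both (medians 2.94 and 2.65), and SPRR and LCE genes for 9 of 15 in both (medians 2.88 and 2.79, adjusted p = 7.25e-12 and 3.52e-11). Proteases and wound genes rose for 12 of 23 in both (adjusted p = 1.54e-08 and 2.61e-08), with MMP12 at 5.01 and 4.68 (4.71 and 4.38 with values under 4 set to 4) and PLAT, which activates plasminogen, at 3.83 and 4.32. The IL-1 family had 9 of 15 higher and 1 lower with SA.IL17 and 8 higher with SP.IL17 (adjusted p = 6.95e-09 and 9.70e-09), and other cytokines had 10 of 20 higher in both (adjusted p = 3.17e-07 and 3.23e-07). All these calls held with an estimated correlation (adjusted p at most 0.00238), as did the metal-binding metallothioneins, 5 and 3 of 7 higher (medians 1.08 and 0.87, adjusted p = 0.0226 and 0.0330 with an estimated correlation). Cell cycle genes had 8 of 30 higher and 1 lower with SA.IL17 and 10 higher with SP.IL17 (adjusted p = 0.0109 and 1.55e-04, but adjusted p = 0.428 and 0.235 with an estimated correlation). Interferon-response genes had 1 of 32 higher and 5 lower in both (adjusted p = 0.146 with SA.IL17, and 0.00785 with SP.IL17, but adjusted p = 0.624 with an estimated correlation for the latter). Of 13 fibroblast markers 2 were lower and 1 higher in each (adjusted p = 0.637 and 0.293), with COL1A2 at -2.28, LUM at -1.74 and FAP at 1.36 with SA.IL17.

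Against the bacterium alone, IL17 changed 1104 genes on top of SA (639 higher, 465 lower) and 816 on top of SP (579 higher, 237 lower). The count on top of SP was 957 without SP.IL17 replicate 1 and 725 without SP.IL17 replicate 2. IL19 (7.34 and 7.67), NDP (6.88 and 6.37), COXFA4L3 (6.40 and 5.57), CEACAM6 (6.37 and 5.91) and SPRR2C (5.78 and 5.67) led both contrasts, and IL23A rose by 5.09 and 4.52. IGFBP5 (-4.45 and -3.76), ASPN (-4.36 and -3.84), SELENOP (-5.00 and -3.37) and DAPL1 (-3.47 and -3.21) were among the lowest, with TLR3 (-3.39) on top of SA and HSPB3 (-2.85) on top of SP. Setting values under 4 to 4 gave 6.14 and 5.57 for NDP and -3.21 for TLR3. The psoriasis list had 23 and 22 of 30 members higher and none lower (medians 2.12 and 1.99, adjusted p = 1.60e-27 and 8.56e-31, adjusted p = 9.10e-06 and 4.03e-06 with an estimated correlation).

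Between SA.IL17 and SP.IL17, 21 genes differed, 10 higher and 11 lower. With SA.IL17, CXCL10 was 1.58 higher (adjusted p = 0.00558), CXCL11 1.46 (adjusted p = 0.0434), IGDCC4 1.33, the glucose transporter gene SLC2A3 1.25 and the BMP antagonist gene GREM1 1.25. SELENOP was 1.68 lower (-1.68), TLR3 -1.43, NAP1L2 -1.29, RNFT2 -1.11 and the DNA glycosylase gene NEIL3 -1.08. Setting values under 4 to 4 gave 1.25 for CXCL11 and -1.25 for TLR3. Of 14 chemokines for other leukocytes 2 were higher (adjusted p = 0.00202, but adjusted p = 0.148 with an estimated correlation). Median centring gave 15 higher and 6 lower genes. The count was 33 without SA.IL17 replicate 2, 7 without SP.IL17 replicate 1, 48 without SP.IL17 replicate 2, and 3 when only these 2 groups were fitted.

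**Figure D3:**
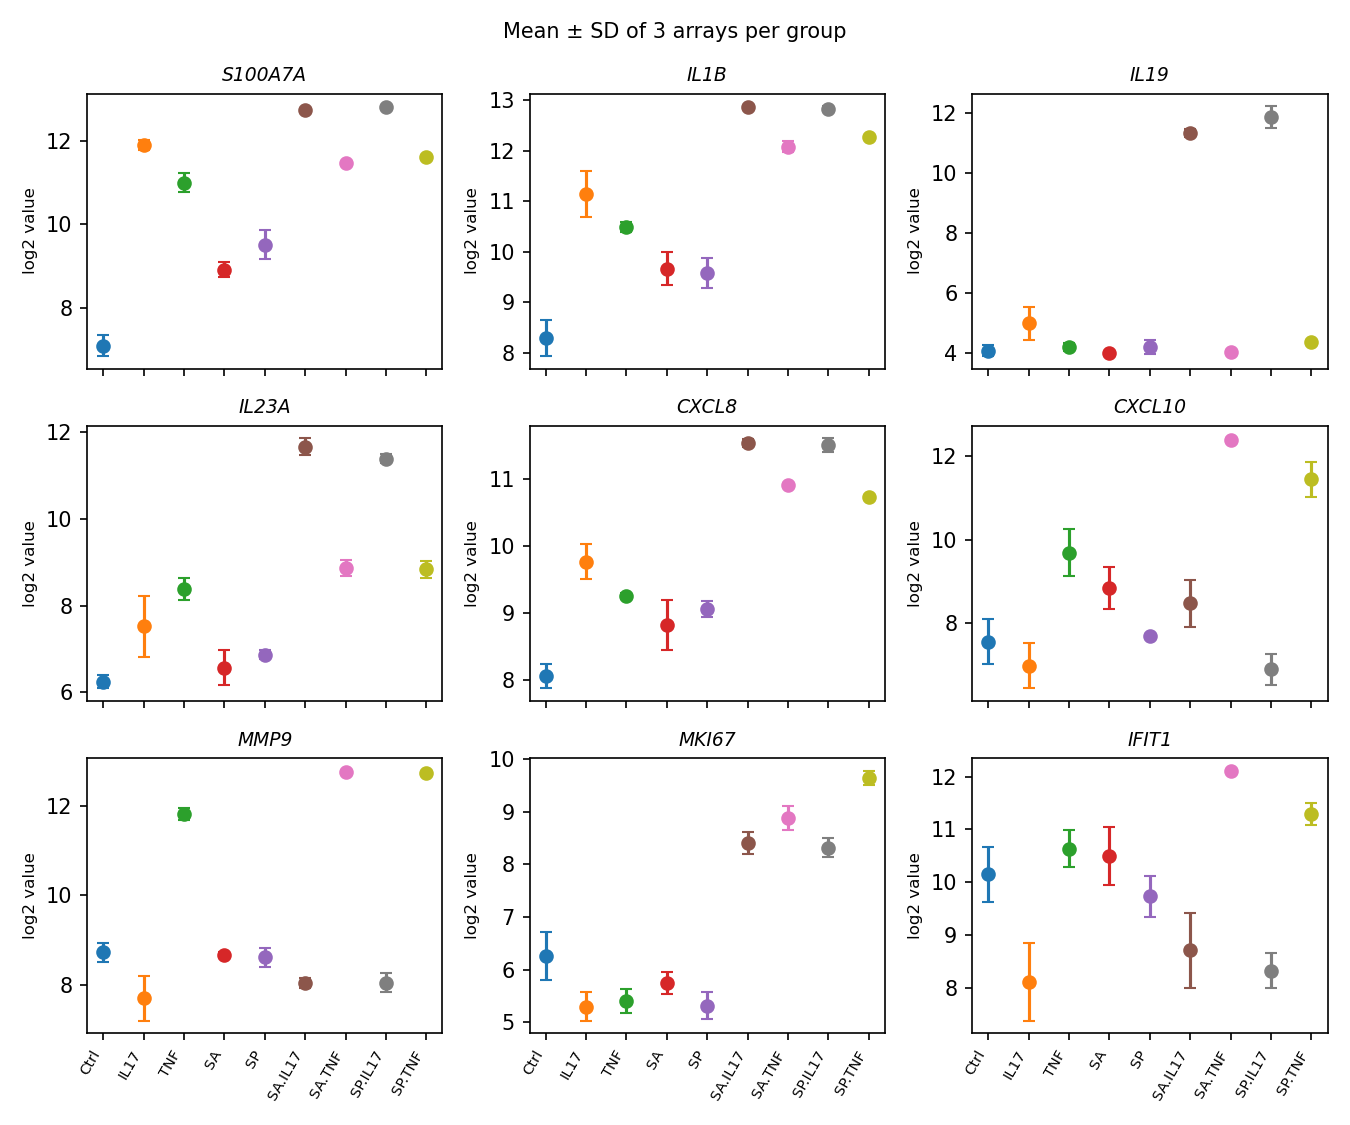
Deposited log2 expression values of 9 named genes, picked after their values had been seen, in the 9 groups (means with SDs as error bars, n = 3 arrays per group). IL19 lies at 11.4 and 11.9 in SA.IL17 and SP.IL17 and at or below 5.00 in all other groups.

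S. aureus with TNF-α was led by a chemokine gene and a cytokine receptor gene. CXCL11 rose by 6.65 ± 0.45 (adjusted p = 7.93e-11) from a control mean of 4.17 ± 0.78 (SD, n = 3), at the background level, IL1R2, a decoy receptor for IL-1, 70.7-fold (6.15 ± 0.25), CXCL6 by 5.64, MX2 by 5.03 ± 0.37, CXCL10 by 4.85 ± 0.34, the lysosomal protease gene CTSS by 4.84, IL1F10 by 4.71, IL36B by 4.68, COXFA4L3 by 4.62 and S100A12 by 4.61. MMP9 rose by 4.05, IL1B by 3.78, IL6 by 2.90, MKI67 by 2.62, FLG by 2.58 and IFIT1 by 1.96. STC2, which encodes stanniocalcin-2, fell by 4.5 ± 0.49, TNFSF11, which encodes the osteoclast factor RANKL, by 3.75, PELI2 by 3.67, PAPPA2, a protease that cleaves IGF-binding proteins, by 3.35, IGFBP5 by 3.03 and ECM2 by 2.83. The SA.TNF arrays varied widely for STC2, at 6.48 ± 1.6 (SD, n = 3) against 10.98 ± 0.12 in control, so its size is uncertain. CXCL6 and IL36B had control means under 4, and TNFSF11 and PELI2 lay under it with SA.TNF: setting values under 4 to 4 gave 5.07, 4.42, -2.90 and -2.98, and 6.48 for CXCL11. IL19 did not pass (-0.05), nor did CCL20 (0.67).

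S. pyogenes with TNF-α, the only stimulated group that shares the controls' description number, gave IL1R2 at 6.17 ± 0.25 (72.1-fold), CXCL11 at 5.11 ± 0.45, CXCL6 at 4.87, S100A7A at 4.52, IL1F10 at 4.49, LINC01127 at 4.48, S100A12 at 4.47 and CTSS at 4.21, with the mitotic genes DLGAP5 at 4.12 ± 0.23 and KIF18B at 4.07. MKI67 rose 10.4-fold (3.38 ± 0.20, adjusted p = 9.24e-12), MMP9 by 4.01, IL1B by 3.96 and CXCL10 by 3.90. TNFSF11 fell by 3.91 ± 0.24, PELI2 by 3.38, C4orf54 by 3.37, IGFBP5 by 3.32, PAPPA2 by 3.10 and ECRG4 by 2.72. Setting values under 4 to 4 gave 4.93 for CXCL11, 4.30 for CXCL6, -2.90 for TNFSF11, -2.98 for PELI2 and -1.53 for ECRG4. The 2 combinations with TNF shared 572 higher and 232 lower genes, against 26.9 and 5.39 expected of independent lists. Their covariance was 0.284 against 0.00546 simulated for shared controls.

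With SA.TNF and SP.TNF, 18 and 20 of 30 genes of the psoriasis list rose (medians 1.65 and 1.67, adjusted p = 1.93e-19 and 2.95e-21), 10 and 9 of 25 NF-kB targets (adjusted p = 1.71e-15 and 3.67e-16), 7 and 8 of 14 chemokines for other leukocytes (adjusted p = 1.27e-06 and 1.99e-05), 13 and 13 of 23 proteases (adjusted p = 6.16e-12 and 8.76e-11) and 9 and 8 of 15 SPRR and LCE genes (adjusted p = 2.37e-09 and 7.41e-09). Cell cycle genes rose for 18 and 21 of 30 (medians 1.16 and 1.73, adjusted p = 3.11e-12 and 2.16e-20), with RRM2 at 2.78 and 3.49 and CDK1 at 2.62 and 3.32. These calls held with an estimated correlation (adjusted p at most 0.0267). Interferon-response genes rose for 25 and 18 of 32, in SP.TNF for 19 adjusted over the list alone (medians 1.91 and 1.19, adjusted p = 1.93e-19 and 7.06e-12, but adjusted p = 0.0582 and 0.141 with an estimated correlation). Unfolded protein and amino acid stress genes fell for 10 and 5 of 24 (adjusted p = 3.75e-05 and 0.00148, but adjusted p = 0.197 and 0.304 with an estimated correlation). With SA.TNF these included ASNS and PHGDH, enzymes of asparagine and serine synthesis (-2.33 and -2.26), and the transcription factor gene ATF3 (-1.80).

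As markers of other cell types, 5 of 13 fibroblast markers were higher with SA.TNF and 4 with SP.TNF (medians 0.75 and 0.79, adjusted p = 0.00434 and 0.00504, but adjusted p = 0.180 and 0.190 with an estimated correlation), PDGFRA at 2.40 and 2.72 and THY1 at 1.80 and 1.65. No marker of this list is in another list. Of 8 endothelial markers 2 were higher in each (adjusted p = 0.478 and 0.421), ROBO4 at 3.10 and 3.04, and of 10 leukocyte markers 2 in each (adjusted p = 0.531 and 0.453), with medians of -0.08 and -0.01 although the means (0.24 and 0.21) and the tests pointed upwards. The endothelial median was likewise -0.01 in SP.TNF against a mean of 0.44. Of 9 melanocyte markers 1, MITF, was lower in each (-1.56 and -1.37, adjusted p = 0.521 and 0.546). The 3' minus 5' difference of GAPDH, a sign of RNA quality, averaged 0.32 in control, 0.36 with IL17, 0.34 with TNF, 0.29 with SA, 0.28 with SP, and 0.24 to 0.27 in the 4 combinations. That of ACTB averaged 0.92 in control, 0.95 to 1.12 with single stimuli and 0.95 to 1.18 in the combinations. These averages hide a spread within the IL17 group. IL17 replicate 2 had the highest difference of any array for GAPDH (0.47) and for ACTB (1.46). It also had the lowest weight (0.283) in the fit with array weights. In that fit, IL17 against control gave 161 genes, and 145 of the 177 calls of the fit used were shared. The cause of the low weight was not tested.

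Against the bacterium alone, TNF changed 986 genes on top of SA (729 higher, 257 lower) and 867 on top of SP (642 higher, 225 lower). IL1R2 (5.59 and 5.90), CXCL11 (5.07 and 4.89) and LINC01127 (4.25 and 4.52) were among the highest in both, with CXCL6 (5.25) and COXFA4L3 (4.39) on top of SA and DLGAP5 (4.85) and KIF18B (4.48) on top of SP. MMP9 rose by 4.10 and 4.12 and MKI67 by 3.13 and 4.32. PELI2 (-3.95 and -3.18), PAPPA2 (-3.24 and -3.18), C4orf54 (-3.08 and -3.79) and IGFBP5 (-3.02 and -2.94) were among the lowest in both. Setting values under 4 to 4 gave 5.08 for CXCL6, 4.42 for DLGAP5, 4.11 for KIF18B and -3.27 and -2.78 for PELI2. The psoriasis list had 16 and 14 of 30 members higher (medians 1.06 and 0.91, adjusted p = 1.88e-14 and 1.98e-14, adjusted p = 3.73e-04 and 3.95e-04 with an estimated correlation). Cell cycle genes had 19 and 21 of 30 higher (adjusted p = 0.0188 and 0.00436 with an estimated correlation). Fibroblast markers had 4 and 6 of 13 higher (adjusted p = 0.00229 and 2.82e-04, but adjusted p = 0.165 and 0.112 with an estimated correlation).

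The combinations of S. aureus with IL-17A and with TNF-α, which share a description number, differed in 1145 genes, 387 higher and 758 lower with IL17. With SA.IL17, IL19 was higher by 7.31, SPRR2C by 4.95, the retinol dehydrogenase gene DHRS9 by 4.67, STC2 by 4.32 (with an SD of 1.6 over the SA.TNF arrays), NDP by 4.03, IL23A by 2.80 and CCL20 by 2.36. CXCL11 (-5.39), SAMD9L (-5.21), MX2 (-5.03), TLR3 (-4.81, and -4.62 with values under 4 set to 4), MMP9 (-4.72), CXCL10 (-3.93) and IFIT1 (-3.39) were lower. Of 32 interferon-response genes 28 were lower with IL17 (median -2.49, adjusted p = 5.62e-19, but adjusted p = 0.0863 with an estimated correlation), as were 12 of 30 cell cycle genes (median -0.84, adjusted p = 2.66e-09, but adjusted p = 0.0770 with an estimated correlation). The psoriasis list had 13 genes higher and 1 lower (median 0.72, adjusted p = 2.66e-09, adjusted p = 0.00864 with an estimated correlation) and the antimicrobial list 5 of 16 higher (adjusted p = 1.71e-06, adjusted p = 0.0446 with an estimated correlation). Of 13 fibroblast markers 7 were lower with IL17 (median -1.04, adjusted p = 0.00429, but adjusted p = 0.209 with an estimated correlation). Median centring gave 506 higher and 604 lower genes and moved the median of all genes by 0.14.

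The interactions asked whether a combination differed from the summed changes of its parts. With IL17 they passed for 668 genes with SA (452 higher, 216 lower) and 457 with SP (381 higher, 76 lower). IL19 exceeded the sum by 6.43 and 6.76, NDP by 5.94 and 5.43, SOST, an inhibitor of Wnt signalling, by 5.31 and 4.51, CEACAM6 by 4.68 and 4.22, MKI67 by 3.61 and 3.97, IL23A by 3.83 and 3.25, IL6 by 2.82 and 2.79 and IL17C by 1.75 and 1.78. SOST lay under the background level of 4 in control, IL17, SA and SP, and NDP in control, SA and SP. With values under 4 set to 4, the interactions of SOST were 3.83 and 3.35, of NDP 5.91 and 5.34, and of CEACAM6 4.78 and 4.33. ASPN (-3.37 and -2.85) and IGFBP5 (-2.97 and -2.27) lay below it, as did SELENOP with SA (-3.79). The psoriasis list lay above the sum (10 of 30 higher and none lower with SA, 9 higher and 2 lower with SP, medians 0.50 and 0.30, adjusted p = 9.52e-06 and 1.30e-04, adjusted p = 0.0221 and 0.0409 with an estimated correlation). So did other cytokines (7 and 8 of 20, adjusted p = 0.00590 and 0.00411 with an estimated correlation) and proteases (8 of 23 in both, with SP 9 adjusted over the list alone, adjusted p = 0.00590 and 0.00411 with an estimated correlation). The probe set kept for S100A7A gave an interaction of -1.52 with SP, while its probe set of largest interquartile range gave 0.67. S100A7 lay below the sum with SP (-1.12), with means of 10.94 in control, 12.24 with SP, 12.99 with IL17 and 13.18 with SP.IL17, and whether its signal was saturated was not tested.

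With TNF, the interactions passed for 568 genes with SA (451 higher, 117 lower) and 530 with SP (419 higher, 111 lower), and genes of the cell cycle led both. DLGAP5 exceeded the sum by 5.06 and 6.04, RRM2 by 4.63 and 5.40, CDK1 by 4.46 and 5.22, DEPDC1 by 4.15 and 5.29, TOP2A by 4.02 and 5.31 and MKI67 by 3.99 and 5.18. With values under 4 set to 4, DLGAP5 gave 4.08 and 4.83, under RRM2 and CDK1 in both, and DEPDC1 3.64 and 4.77. PAPPA2 lay below it (-2.78 and -2.71), as did STC2 with SA (-3.47, with an SD of 1.6 over the SA.TNF arrays), and CCL20 (-1.52 and -1.18). Of 30 cell cycle genes 17 and 21 were higher (medians 1.61 and 2.26, adjusted p = 2.03e-20 and 2.06e-29, adjusted p = 0.0383 and 0.00678 with an estimated correlation). Interferon-response genes were higher for 12 and 9 of 32, and for 14 and 11 adjusted over the list alone (adjusted p = 2.51e-09 and 1.21e-05, but adjusted p = 0.451 and 0.734 with an estimated correlation). The psoriasis list did not pass, with 1 of 30 higher and 2 lower with SA and 4 lower with SP (medians -0.10 and -0.12, adjusted p = 0.494 and 0.116). Fibroblast markers had 3 of 13 higher and 1 lower in both, with SA 4 higher adjusted over the list alone (adjusted p = 0.0407 and 0.0125, but adjusted p = 0.488 and 0.601 with an estimated correlation). Median centring gave 362 higher and 165 lower genes with SA and 321 and 161 with SP, and moved the medians of all genes by -0.12 and -0.12.

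**Figure D4:**
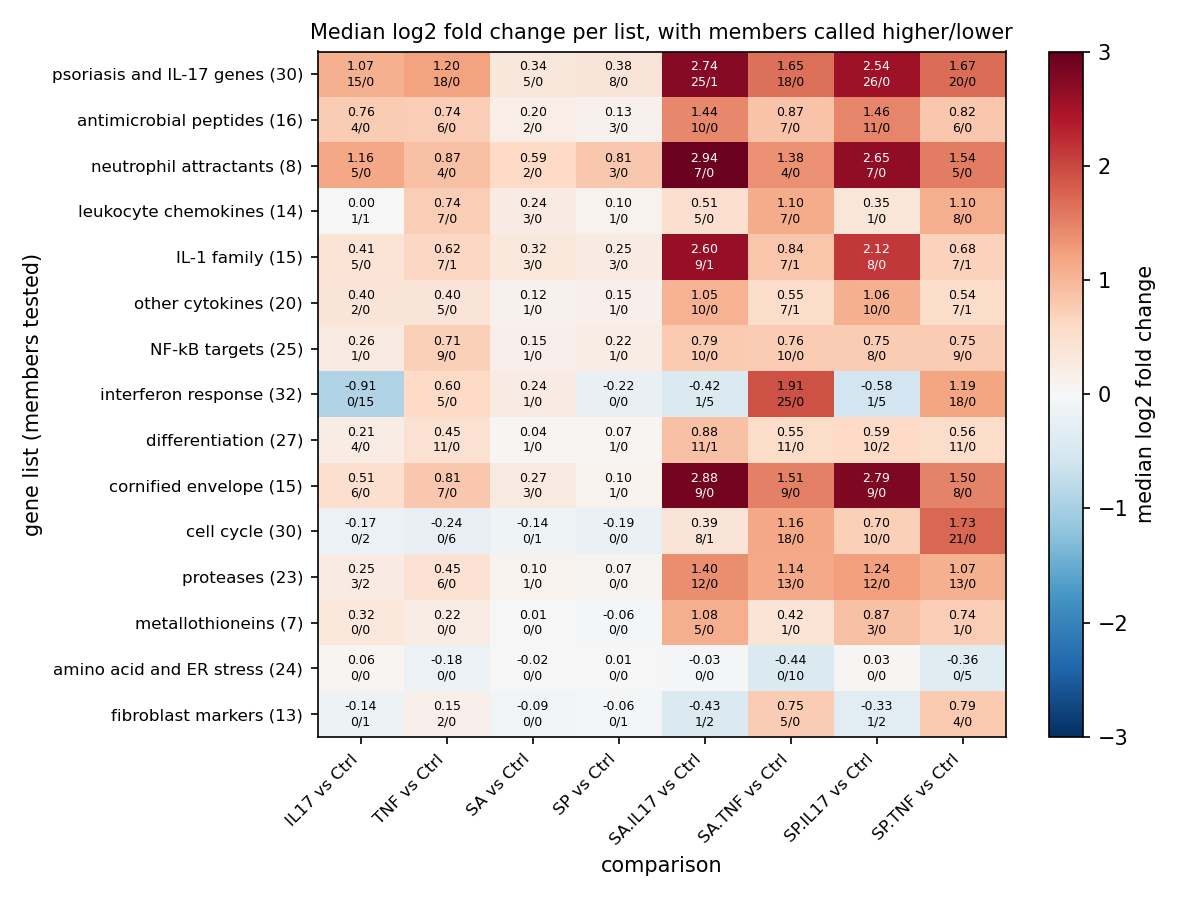
Median log2 fold change against control (colour and printed value) of 15 of the 36 gene lists, picked after the values had been seen, in the 8 stimulated groups (n = 3 arrays each). Cell cycle medians are between -0.24 and -0.14 with a single stimulus and between 0.39 and 1.73 in the combinations, and the interferon-response median runs from -0.91 with IL17 to 1.91 with SA.TNF.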

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

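The test of brightness from control and single stimuli and the tests of the description number for the SAxTNF interaction, the cell cycle genes and the IL17 against TNF interferon genes were chosen after the results were seen, and so were GAPDH and then ACTB as measures of RNA quality.

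The results below were picked out because a combination's change from control differed from the summed changes of its bacterium and its cytokine by the interaction test in limma. These were 668 genes for SA with IL17, 568 for SA with TNF, 457 for SP with IL17 and 530 for SP with TNF. The shared changes were 323 higher and 64 lower genes between the 2 interactions with IL17, and 322 higher and 77 lower between those with TNF. Each pair shares its control and cytokine arrays, and simulated combinations at the sum of the single changes, with the same sharing, gave at most 0 shared genes either way in 100 draws. Combinations at the sum give almost no interaction calls, so these counts cannot show how much overlap the shared arrays add among called genes. The covariances were 0.170 with IL17 and 0.186 with TNF, against 0.0109 and 0.0109 simulated. Some sizes below rest on group means under the background level of 4. With values under 4 set to 4, the interactions with IL17 were 3.83 (SA) and 3.35 (SP) for SOST, 4.78 and 4.33 for CEACAM6 and, with SA, -2.53 for TLCD4, and those with TNF 4.08 and 4.83 for DLGAP5, 3.64 and 4.77 for DEPDC1, -1.79 for PELI2 with SA and -1.40 for TLCD4 with SP. DLGAP5 then lies under RRM2 and CDK1 in both.

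For SA with IL17, the largest differences above the sum were IL19 (6.43), NDP (5.94), SOST (5.31), CEACAM6 (4.68) and LINC00302 (4.26), and below it SELENOP (-3.79), ASPN (-3.37), IGFBP5 (-2.97), TLCD4 (-2.68) and GASK1B (-2.51). In the key panel IL23A (3.83), MKI67 (3.61), IL6 (2.82), IL17C (1.75) and CXCL8 (1.00) passed. For SP with IL17, these were IL19 (6.76), NDP (5.43), SOST (4.51), CEACAM6 (4.22) and MKI67 (3.97), and below the sum ASPN (-2.85), PDK4 (-2.47), which restrains pyruvate use, C4orf54 (-2.30), IGFBP5 (-2.27) and LUM (-2.23). In the key panel IL23A (3.25), IL6 (2.79), IL17C (1.78), S100A7 (-1.12) and FLG (-1.08) passed.

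For SA with TNF, genes of the cell cycle led: DLGAP5 (5.06), RRM2 (4.63), CDK1 (4.46), DEPDC1 (4.15) and TOP2A (4.02). Below the sum lay STC2 (-3.47, with an SD of 1.6 over the SA.TNF arrays), PAPPA2 (-2.78), ECM2 (-2.71), LINC02806 (-2.49) and PELI2 (-2.48). In the key panel MKI67 (3.99), CXCL10 (1.42) and CCL20 (-1.52) passed. For SP with TNF, DLGAP5 (6.04), RRM2 (5.40), TOP2A (5.31), DEPDC1 (5.29) and CDK1 (5.22) led, with PAPPA2 (-2.71), C4orf54 (-2.36), TLCD4 (-2.15), the lipoprotein receptor gene OLR1 (-2.14) and the epithelial transcription factor gene ELF3 (-2.13) below the sum. In the key panel MKI67 (5.18), CXCL10 (1.62), MMP9 (1.02), S100A7 (-1.22) and CCL20 (-1.18) passed. With IL17, with TNF and in the combinations, S100A7 had means of 12.99 to 13.22, and whether its signal was saturated there, which gives values below the sum, was not tested.

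Probe sets that name no single gene were left out of the comparisons of genes, and some of them stood above control by the same test. Of 9211 such probe sets, 4 were higher and 1 lower with SA, 5 and 5 with SP, 16 and 11 with IL17, 62 and 26 with TNF, 237 and 186 with SA.IL17, 242 and 124 with SA.TNF, 143 and 178 with SP.IL17, and 225 and 118 with SP.TNF.

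Past the 2-fold minimum, 67.7% to 83.4% of the interaction genes lay above the sum of the single effects, while at adjusted p alone the percentages higher were 43 and 48.04 with IL17 and 52.12 and 50.74 with TNF (SA and SP in each pair). Compression of dim genes by the GCRMA background correction stays open: among genes with a mean of at least 8 the lowest of the 4 percentages higher was 65.55 (lower Wilson bound 58.88), but that mean takes in genes the combinations raised past 8, and with the mean over control and single stimuli, which leaves such genes out, it was 52.69 (lower bound 45.53), for SA with IL17. The others were then 55.38 (46.81) for SA with TNF, 64.42 (54.86) for SP with IL17 and 60.16 (51.33) for SP with TNF. If the description number were the whole cause of the SP with TNF interaction, the summed IL17 and SA changes would offset it, but over the 419 higher genes that share had a 75th percentile of 0.4775 and a median of 0.207, and SP.TNF against control, within 1 number, had a median of 1.205 with 248 of them called higher, which argues only against the number as the whole cause, close to its bound of 0.5 and assuming that IL17 and SA do not raise these genes themselves. For SA with TNF, 71.4% of the higher genes were also higher for SP with TNF, which shares its control and TNF arrays, between the bounds of 25 and 75 set for and against the number, and for the interactions with IL17 the number and the groups cannot be told apart. A response of the cells to both stimuli at once, the compression, a difference tied to the number (for SP with TNF only as a part), or several of these may therefore underlie the pattern.

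Cell cycle genes were below control in median with each single stimulus (-0.138 to -0.240) and above it in the combinations (0.387 to 1.73). Few members were called lower with a single stimulus (1 with SA, 0 with SP, 2 with IL17 and 6 with TNF). With SA.IL17, 8 were higher and 1 lower, and with SP.IL17 10 were higher. With an estimated correlation the list call held for SA.TNF and SP.TNF, and was lost for SP, TNF, SA.IL17 and SP.IL17. A difference tied to the description number does not account for SP.TNF, which shares its number with the controls and had 21 of 30 members higher. With each array's GAPDH 3' minus 5' difference as a covariate for RNA quality, 21 members were still higher, although that covariate had a slope past the adjusted p in 0 genes by limma (2113 at an unadjusted p under 0.05), so it removed little, and with that of ACTB (slope past the adjusted p in 168 genes) 20 members were. Culture density or growth stage was not tested and stays open, as does the number for the other 3 combinations. A larger share of dividing cells in SP.TNF may be the source.

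Interferon-response genes were lower with IL17 than with TNF, both alone and with SA. Both contrasts lie within 1 description number, and the lower of the 2 counts was 24 of 32 members, which the number alone would not give. For IL17 against control, the fewest members called lower without 1 control array was 13, so no single control array accounts for it, but this contrast crosses 2 numbers and they cannot be told apart from the groups. The list's camera calls, that for SA.IL17 against SA.TNF included, were lost with an estimated correlation (adjusted p = 0.0846 for IL17 against TNF and 0.153 for IL17 against control), so these members may vary together for a reason the groups do not hold. Apart from the 4 interferon genes given under the other observations, no source of interferon was tested.

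For each of the 16 contrasts between 2 groups, only 10 splits of the 6 arrays exist, so the share of splits as large is never under 0.1. The real split alone, 1 of the 10 splits, reached its count in each, and the highest of the other splits called 0 genes, except 1 for SP against control (25 in the real split) and 2 for SA.IL17 against SP.IL17 (21). For the F test, 1 of 100 splits, the real grouping itself, reached 13583 genes, and the highest of the drawn ones called 0. This sets the groups apart from random relabellings of these arrays. Regrouping moves the group differences into the spread within groups, which keeps such counts low. Where arrays of a group share a culture, chance differences between cultures are not excluded. For the interactions, with the real split again counted among the 100, 4 splits reached the 568 genes of SA with TNF (highest other 1114), 9 the 668 of SA with IL17 (highest other 1485), 10 the 457 of SP with IL17 (highest other 1204) and 12 the 530 of SP with TNF (highest other 1564). Splits that call about 2 to 3 times the real count point to a structure of the samples: regrouping moves the large differences between combinations and other groups into the contrast, so these splits say nothing for or against chance in the interactions.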

How the results depend on the processing

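All alternatives named here were fixed in advance, except the check of list medians under other scalings, the fits with values under 4 set to 4, and the replicate block. The labels number the arrays through the whole series, so no groups share replicate numbers and no pairing is stated. As a hint from the data, not the design, deviations from the group means correlated at 0.152 on average between arrays of the same order in their groups and at -0.0754 otherwise, with 21 of 27 arrays closest to their own order and 26 of 36 pairs of groups over 0.1 (lowest 0.00346). With this order as a replicate block, SA vs SP gave 6 genes in place of 1, 0 calls by limma were lost in any contrast, and the other counts stayed within 1.5 times. The description number could be fitted as a fixed block only in an additive model of bacterium, cytokine and number over all 27 arrays, for SA vs SP and IL17 vs TNF. That model pools single and combination groups, so it estimates an average difference between the bacteria or the cytokines, which is another quantity than the contrast of the single groups, and both single-group contrasts lie within 1 number. With 3 arrays a group, leaving 1 out leaves 2, and the fit over all arrays carries the spread. Values near background (24.0% at or under 4) limit folds of dim genes. Where the causes of the shifts below are not given by the settings themselves, the cause was not tested.

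Counts of changed genes stayed within 1.5 times under a filter at 5, no filter, and trend and robust eBayes. Under array weights (5), a filter at 6 (3), the mean of a gene's probe sets (2), the probe set of largest interquartile range (3), quantile normalization (2) and median centring (4), the 1 count that moved was SA vs SP (1 gene in the fit used). With only the groups compared, SA vs SP gave 0 by limma (in the full fit 1268 of 16854 at an unadjusted p under 0.05, where chance alone gives a share of about 0.05) and SA.IL17 vs SP.IL17 3 in place of 21. In the additive model with the description number as a fixed block, SA vs SP gave 7 and IL17 vs TNF 586. With values under 4 set to 4, the interactions called 636 (SA, IL17), 542 (SA, TNF), 432 (SP, IL17) and 508 (SP, TNF) genes, and none of the 20 counts moved by over 1.5 times.

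The setting with every probe set counts probe sets in place of genes, those without a single gene included. Against control it gave 55 (SA), 46 (SP), 301 (IL17), 676 (TNF), 2684 (SA.IL17), 2213 (SA.TNF), 2047 (SP.IL17) and 1997 (SP.TNF). It gave 2260 for SA.IL17 vs SA, 2030 for SA.TNF vs SA, 1760 for SP.IL17 vs SP, 1778 for SP.TNF vs SP, 7 for SA vs SP, 664 for IL17 vs TNF, 61 for SA.IL17 vs SP.IL17 and 2401 for SA.IL17 vs SA.TNF. Interactions gave 1411 (SA, IL17), 1257 (SA, TNF), 904 (SP, IL17) and 1143 (SP, TNF), and the F test 33068.

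Without the fold minimum, by construction, counts rose. Adjusted p alone gave against control 1979 (SA), 1321 (SP), 5059 (IL17), 5679 (TNF), 9130 (SA.IL17), 8476 (SA.TNF), 8267 (SP.IL17) and 7520 (SP.TNF). It gave 7930 for SA.IL17 vs SA, 7875 for SA.TNF vs SA, 6547 for SP.IL17 vs SP, 7394 for SP.TNF vs SP, 16 for SA vs SP, 4596 for IL17 vs TNF, 1597 for SA.IL17 vs SP.IL17 and 8565 for SA.IL17 vs SA.TNF, and for the interactions 5328 (SA, IL17), 5754 (SA, TNF), 3628 (SP, IL17) and 5625 (SP, TNF). A minimum of 1.5-fold gave against control 142 (SA), 107 (SP), 632 (IL17), 1024 (TNF), 3018 (SA.IL17), 2425 (SA.TNF), 2316 (SP.IL17) and 2185 (SP.TNF). It gave 2561 for SA.IL17 vs SA, 2309 for SA.TNF vs SA, 1895 for SP.IL17 vs SP, 2116 for SP.TNF vs SP, 9 for SA vs SP, 999 for IL17 vs TNF, 205 for SA.IL17 vs SP.IL17 and 2682 for SA.IL17 vs SA.TNF, and for the interactions 1877 (SA, IL17), 1776 (SA, TNF), 1215 (SP, IL17) and 1671 (SP, TNF).

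Leaving out each array in turn gave 20 to 39 genes for SP vs Ctrl (39 without Ctrl replicate 2), 0 to 2 for SA vs SP (0 without SA replicate 2, 2 without SA replicate 1) and 7 to 48 for SA.IL17 vs SP.IL17 (7 without SP.IL17 replicate 1, 33 without SA.IL17 replicate 2 and 48 without SP.IL17 replicate 2). The counts of all other contrasts stayed within 1.5 times. Counts with SP.IL17 were highest without SP.IL17 replicate 1 and lowest without its replicate 2. They were 1107 and 894 against control, 957 and 725 against SP, and 547 and 390 for the interaction of SP with IL17.

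Of 3137 values of named genes, 1283 were called, and 1023 of these kept their call under all alternatives. Among alternatives of uncalled values, 372 had the other sign, 1 of them past the threshold (IL23A). Of called values, S100A7A turned in 2 interactions and RRM2 in 1 contrast. S100A7A gave 0.021 for SA with TNF and 0.666 for SP with IL17 in the probe set of largest interquartile range, against -1.35 and -1.52. In the additive model, the pooled difference between IL17 and TNF was 1.013 for IL23A against -0.86 between the single groups, and -0.011 for RRM2 against 1.42. Among lists, the estimated correlation ended 166 of the calls made by camera and left 514 results the same. The test fry gained 146 calls, lost 22, left 511 and turned 1, heat shock in SA.TNF vs Ctrl (adjusted p = 0.0149, down). Under another scaling, list medians changed sign in 114 cases, the largest of size 0.123, and 2 of these lists had been called by camera.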

Other observations

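The tests of aryl hydrocarbon receptor targets and of list medians under other scalings were chosen after the results were seen.

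With SA.IL17, metallothioneins aside, immediate early genes had 5 of 24 members higher (FOSB 1.82; adjusted p = 7.79e-08, but adjusted p = 0.0683 with an estimated correlation) and with SP.IL17 4 (adjusted p = 2.48e-06, but adjusted p = 0.111 with an estimated correlation). Hypoxia and glycolysis genes had 2 of 25 higher with SA.IL17, the glucose transporter gene SLC2A3 at 1.49 (adjusted p = 1.74e-04, adjusted p = 0.0116 with an estimated correlation). NRF2 targets had 1 of 18 higher, the haem oxygenase gene HMOX1 (1.56), and 2 lower, NQO1 (-1.27) and AKR1B10 (-1.39), with SA.IL17 (adjusted p = 0.519). Targets of p53 had 1 of 16 lower, the DNA repair gene DDB2 (-1.54), with SA.IL17 (adjusted p = 0.00878, but adjusted p = 0.0683 with an estimated correlation) and 1 lower with SP.IL17 (adjusted p = 0.00302, adjusted p = 0.0410 with an estimated correlation). Cholesterol synthesis had 1 of 18 higher with SA.TNF, ACAT2 (1.02; adjusted p = 1.36e-04, but adjusted p = 0.208 with an estimated correlation). Ribosomal protein genes had 0 of 22 called with SA.TNF by limma (median -0.11, adjusted p = 0.00100, but adjusted p = 0.106 with an estimated correlation), and heat shock genes 0 of 11 (median 0.09 and mean -0.04, adjusted p = 0.938).

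MHC class I genes had 2 of 16 higher with SA.TNF, the immunoproteasome gene PSMB9 (1.70) and the peptide-trimming gene ERAP2 (1.67; adjusted p = 1.75e-09, adjusted p = 0.00326 with an estimated correlation), and 1 lower with SA.IL17, PSMB9 (-1.40; adjusted p = 0.0671). MHC class II genes had 1 of 8 higher with SA.TNF, CD74 (2.12; adjusted p = 0.955). Complement genes had 3 of 11 higher with SA.TNF, C1R at 2.74 and C1S at 2.09 (adjusted p = 0.00209, but adjusted p = 0.106 with an estimated correlation). Pattern recognition genes had 7 of 30 higher with SA.TNF, AIM2, a sensor of DNA, at 2.33 and TLR2 at 1.94 (adjusted p = 0.0328, but adjusted p = 0.153 with an estimated correlation), with a median of -0.01 against a mean of 0.36. With TNF alone 4 were higher (adjusted p = 0.0135, but adjusted p = 0.111 with an estimated correlation), with a median of -0.01 whose sign turned under another scaling. Cell death genes had 2 of 18 higher with SA.TNF, MLKL (2.58) and RIPK3 (1.51), which act in necroptosis (adjusted p = 0.0533). Kynurenine and nitric oxide genes had 2 of 8 higher with TNF, ARG1 (2.98) and KYNU (2.00; adjusted p = 0.0111, adjusted p = 0.0290 with an estimated correlation). Junction genes had 3 of 21 higher with SA.IL17, CLDN4 at 2.02 (adjusted p = 0.00878, but adjusted p = 0.350 with an estimated correlation). Basal keratinocyte genes had 1 of 15 lower with SA.IL17, KRT15 (-1.43; adjusted p = 0.263).

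Lists with under 5 tested members had no list test. Of 4 interferon genes 0 were called against control by limma, and IFNK exceeded the sum in the interaction of SA with IL17 (1.69) and of SA with TNF (1.34). The 1 tested hyperproliferation keratin, KRT16, lay at 12.9 ± 0.05 (SD, n = 3) in control and differed from it by -0.10 to 0.02, not called in any group. Whether its signal was saturated was not tested.

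CYP1A1 rose with both bacteria, and CYP1B1 (1.29 with SA and 1.08 with SP) is induced through the same receptor. A hypothesis was that a wider set of aryl hydrocarbon receptor targets may rise with them. Of 5 other targets of this receptor, 0 were called higher with SA or SP by limma. With SA, CYP1A2 was at 0.33 (adjusted p = 0.0241), AHRR at 0.29 (0.135), TIPARP at 0.21 (0.0115), ALDH3A1 at 0.02 (0.964) and NQO1 at -0.16 (0.306), and with SP at 0.22 (0.133), 0.21 (0.312), 0.23 (0.00731), 0.10 (0.790) and -0.23 (0.168), with the adjusted p in parentheses. The wider rise of aryl hydrocarbon receptor targets at 2-fold was therefore not seen. Below 2-fold, TIPARP passed the adjusted p with both bacteria and CYP1A2 with SA, so a smaller rise of some targets stays open. CYP1A1 also rose with TNF alone (1.32) and in all 4 combinations, from 1.53 with SP.TNF to 2.49 with SP.IL17. CYP1B1 was called in none of the combinations (-0.133 with SP.TNF to 0.799 with SP.IL17). With SA.IL17 and SP.IL17, ALDH3A1 (-1.62 and -1.13) and NQO1 (-1.27 and -1.20) were called lower.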
